A study of Drosophila melanogaster with 2 samples.

How the data were processed

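The samples were 2 biological replicates, numbered 2 and 3 in the labels, of 1 group. Each was a ChIP-seq library made with an anti-GFP antibody from whole wandering larvae, sexes pooled, of a Drosophila melanogaster line that carries Rel fused to GFP at its C terminus. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels name no second condition and no infection, so no comparison between groups was made. A control alignment entered the authors' peak calling and was not analysed here.

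The deposited files are peak lists in narrowPeak format on builds dm6 and dm3. For each replicate, and for the pooled reads of both, the authors provided a relaxed list of 30000 regions that mixes peaks with background. These lists were the input to the irreproducible discovery rate (IDR) procedure, and a further list holds the peaks the authors kept after it. The deposited signal value of each region is the peak caller's own, relative to the control, and was used only to rank regions within 1 list. The deposited −log10 q of each region was used to describe the lists and to define an added set of regions. Aligner, peak caller and their versions are not given in the sources used here. The files hold no read counts, so the depth of each library is unknown. Relaxed lists are cut at a fixed length, which means that the rank of a region, not its presence, carries information. The regions of a list mostly share 1 width set in peak calling, so overlap depends on that width as well as on the positions of the summits.

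Coordinates are on dm6 and counted from 1. Gene positions came from Ensembl release 115 (BDGP6.54) and sequence from the matching reference assembly. No region ended beyond the end of its reference chromosome. The dm3 lists served only for counts and overlaps, and no coordinates were converted. Genes were the 13945 protein-coding genes on chromosomes 2L, 2R, 3L, 3R, 4 and X, with 19607 annotated transcription start sites (TSS). Each summit was assigned to 1 class in the order promoter (within 500 bp of a TSS), 5′ UTR, coding sequence, 3′ UTR, intron, non-coding gene and intergenic.

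Replicate overlap was the share of the top 2133 regions of replicate 2 that shared at least 1 bp with a top 2133 region of replicate 3, where 2133 is the length of the IDR list. It was compared with 1000 circular shifts of the replicate 3 list within each chromosome, in a one-sided permutation test. Summit classes were compared with 1000 sets of random positions on the same chromosomes, one-sided for the promoter share and two-sided with Benjamini-Hochberg adjustment for the table of classes. For motifs, windows of 100 bp either side of each summit were set against as many random windows from a pool of 300000. These were matched 1 to 1 on GC content within 2 percentage points and on lying within 500 bp of a TSS. Fisher's exact test was two-sided, with Benjamini-Hochberg adjustment over 18 motif strings, 4 of them kB strings, or over the 2080 6-mers. A 6-mer was called enriched at an adjusted p under 0.05 and a ratio of at least 1.5. Ratios of shares had 0.5 added to each count. A gene was counted as bound if an IDR summit lay inside it or up to 1000 bp upstream. The number of bound members of each of 18 gene lists was compared with 10000 random lists matched on gene length in 10 classes (two-sided permutation test, adjusted over the 18 lists). Of 246 list symbols, 4 were matched through older symbols and 1 (lat) was not matched; ribosomal protein genes were taken by name pattern. X and autosomes were compared by an exact binomial test. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Peaks and genes are not independent replicates, so the p-values describe these lists and not the spread between larvae.

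The named genes followed a rule set, with the lists, motifs, tests and most of the alternative settings, before the data were examined. The rule takes the protein-coding gene with the nearest TSS for each of the 25 highest-ranked IDR peaks, and every bound gene of the antimicrobial peptide and Imd lists. It also takes up to 4 bound members with the highest-ranked summits of each other list, and up to 2 unbound members of a list with none. One gene that the rule takes is not reported here. Alternatives left out each replicate in turn, by using the top 2133 regions of the other one. Others kept only the top 1066 IDR peaks, or changed the overlap, list length, build, TSS distance, window, background, motif, gene assignment or matching. Added after the data were seen were the 4236 pooled regions with a q value under 0.05 and matching of lists on 50 length classes. For motifs other than kB, windows of 200 bp, windows 1000 bp from the summits and shuffled windows were added after the results were seen.

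Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap, promoter share, motif, 6-mer and gene list calculations were tested on simulated data. The broad kB string, planted in 2% of the 2133 matched windows, was called in 19 of 20 draws, and planted in 1% in 4 of 20. With none planted it was called in 0 of 20. Both sets of windows in these draws came from the same matched pool, so their shares were alike before planting. If summit windows start from a lower share than matched windows, the power is lower than these draws show. For lists of 15 genes, random lists gave an unadjusted permutation p under 0.05 in 3 of 200 draws. Lists with 9 bound members planted gave such a p in 200 of 200. Gene lists were called on the adjusted p, which these draws did not score, so they do not show the power of that call. The ecdysone list, with 10 of 15 genes bound, had an unadjusted permutation p of 0.0086 but an adjusted p of 0.155. Independent region lists gave a permutation p under 0.05 for overlap in 0 of 20 draws, and lists sharing regions by design in 20 of 20.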

Results

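Rel (Relish) is the NF-κB transcription factor of the Imd branch of Drosophila immunity. ChIP-seq against a GFP tag at the C terminus of the protein was done in whole larvae of the wandering stage, in 2 biological replicates of 1 group. Only forms of Rel that carry this tag can be seen, so the peaks describe tagged protein and not all Rel. The list kept by the authors after IDR held 2133 peaks on dm6 and 2096 on dm3. Peak widths ran from 99 to 470 bp, and 91.4% of the dm6 peaks were 396 bp wide. The authors' signal value ran from 72.5 to 674, with a median of 99.5. The IDR list was identical, region by region, to the 2133 highest-ranked regions of the pooled relaxed list. The depth of the libraries is unknown, since the lists hold no read counts.

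The strongest peaks lay at genes of varied function. The first was in an intron of CG11050 (2L:6612401-6612870, signal 674), and it ranked 1 in both replicates. The peak ranked 2 lay in an intron of ush, a GATA cofactor of blood cell development (2L:480944-481235, signal 562), 1347 bp from the nearest TSS, that of cbt. Peaks 3 and 4 were at the promoters of Ugalt, a UDP-galactose transporter (X:2703756-2704037, summit 48 bp from the TSS), and Tina-1 (2R:24942415-24942702, 155 bp). Peak 5 was intergenic, 5796 bp from eEF1gamma, a translation elongation factor subunit, and peak 6 was intergenic, 1508 bp from CG43389. Peak 7 (3R:31404534-31404799) lay 84 bp from the TSS of PNPase, a mitochondrial RNA exonuclease, and 593 bp from that of Gprk2, which is transcribed away from it.

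Among the 25 highest-ranked peaks, 15 summits lay within 500 bp of a TSS. Besides Ugalt, Tina-1 and PNPase, the genes at these promoters were larp, Chro, CG18549, Gapdh2, ph-p, CG9147, Lpin, CenG1A, CG1888, CG14100, Hsp27 and Syp. They include a glycolytic enzyme (Gapdh2), a Polycomb group protein (ph-p), a phosphatidate phosphatase of the fat body (Lpin) and a small heat shock protein (Hsp27, signal 357, summit 151 bp from the TSS). The remaining summits lay in introns of CG32772, Lk6 and osa, a subunit of the Brahma chromatin remodelling complex. One was in an intron of CG32486, with CG16753 as the nearest TSS, 1 was in a non-coding gene 6079 bp from CG4004, and 1 was intergenic near CG31668.

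The replicates shared most of their strongest regions. Of the top 2133 regions of replicate 2, 1310 (61.4%, 95% interval 59.3 to 63.5) overlapped a top 2133 region of replicate 3. Circular shifts gave a mean of 1.2% and a maximum of 2.48% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Shifted regions do not keep their position relative to genes. The p therefore cannot separate agreement at particular sites from a preference for promoters that both lists share. All of the 100 strongest IDR peaks, among them those at CG11050, ush, imd and Hsp27, lay in the top 2133 of both replicates. Of all IDR peaks, 1280 (60.0%) did so, while 1701 were in that part of the replicate 2 list and 1633 in that of replicate 3. Since the IDR list is ranked on pooled reads, its peaks are not a further independent measurement.

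Summits were concentrated at promoters and nearly absent from coding sequence. Within 500 bp of a TSS lay 888 of the 2133 summits (41.6%, 95% interval 39.5 to 43.8), against 11.5% of random positions, a ratio of 3.62 (one-sided permutation p = 0.001, the smallest that 1000 sets can give). Coding sequence held 1 summit (0.0469%), against 13.9% of random positions (0.234% without replicate 2 and 0.0938% without replicate 3), and 3′ UTRs held 17 (0.797% against 4.49%). Intergenic sequence held 270 summits (12.7% against 28.0%). For each of these 3 classes the two-sided permutation p was 0.002, the smallest possible, with an adjusted p of 0.0035. The 5′ UTRs outside promoters held 27 summits (1.27% against 0.790%, adjusted permutation p = 0.0308). Introns held 874 summits (41.0% against 39.2%), a difference that did not pass the test (adjusted permutation p = 0.117). All these shares are of all summits, and promoters, assigned first, took 41.6% of summits against 11.5% of random positions. This leaves a smaller share for every later class. Summits outside promoters were not compared on their own, so the intron result does not show that introns are at the random level among them. Among the 100 strongest peaks, 53 summits (95% interval 42.8 to 63.1%) lay within 500 bp of a TSS.

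**Figure D1:**
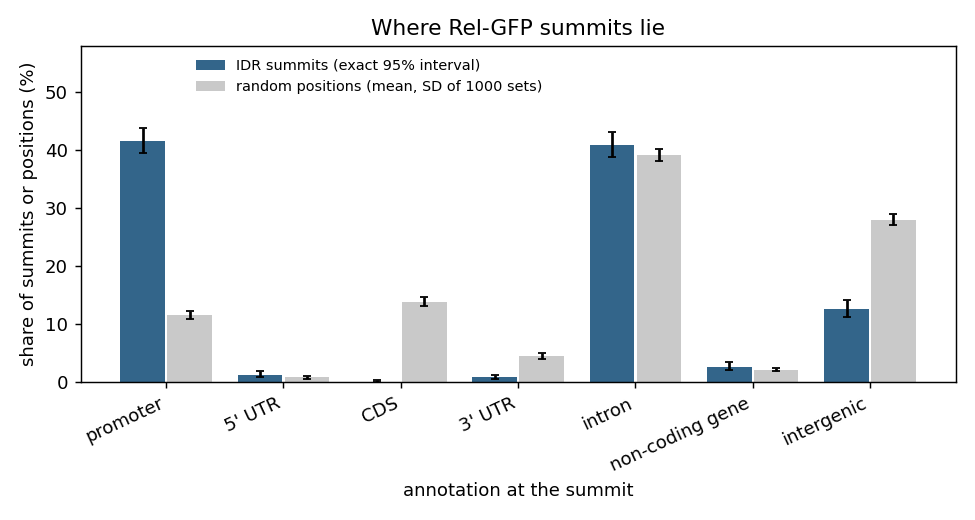
Share of the 2133 IDR summits (blue, with exact 95% intervals) and of random positions (grey, mean and SD of 1000 sets) in each annotation class, in percent. Promoters hold 41.6% of summits against 11.5% of random positions, and coding sequence holds 0.0469% against 13.9%.

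The sequence bound by NF-κB proteins, the kB site, was not more frequent at the summits than in matched sequence. The broad string GGGRNNYYCC occurred in 20 of 2133 summit windows (0.938%, 95% interval 0.574 to 1.44) and in 33 matched windows (1.55%), a ratio of 0.612 (Fisher's exact test, p = 0.0963, adjusted p = 0.248). The shorter string GGGAWTCMC occurred in 3 windows against 5 (4 against 11 without replicate 2). GGGRWTYMC and GGGWWWWYCC occurred in 19 against 13 and in 15 against 12, ratios of 1.44 and 1.24, with adjusted exact p-values of 0.620 and 0.872. Neither ratio was above 1 in every alternative, since they were 0.782 and 0.742 without replicate 2, and 1.05 and 0.514 without replicate 3. Matched windows were drawn anew for each setting, so these changes cannot be put down to the replicates alone. For GGGRWTYMC, counts were 21 against 27 without replicate 2 and 22 against 21 without replicate 3. Its summit counts thus moved less than those of the matched windows. With windows of 200 bp either side, GGGWWWWYCC was less frequent at summits (ratio 0.560, adjusted exact p = 0.0481; range over 9 alternatives 0.0481 to 1). The lowest adjusted p of the broad string over all alternatives, 0.0175, was for windows of 200 bp either side, where it was less frequent at summits (ratio 0.574, adjusted p from 0.0175 to 1 over its 9 alternatives).

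Simple repeats were more frequent at the summits. The string GAGAGAG, bound by GAGA factor, occurred in 234 windows (10.97%, 95% interval 9.68 to 12.4) against 46 (2.16%), a ratio of 5.04 (adjusted exact p = 3.7e-32). Against windows 1000 bp from the same summits, not matched on GC content, of which 4.29% held it, the ratio was 2.56, the lowest of 9 alternatives. CACACACA occurred in 200 windows against 84 (9.38% against 3.94%, ratio 2.37, adjusted exact p = 7.4e-12). The strings of STAT (TTCNNNGAA, 94 against 141, ratio 0.668, adjusted exact p = 0.00884) and C/EBP (TTRCNNAA, 552 against 652, ratio 0.847, adjusted exact p = 0.00453) were less frequent at summits. STAT passed in 6 of 9 alternatives and C/EBP in 4, and neither among the 1066 strongest peaks, at ratios of 0.726 and 0.834 (adjusted exact p = 0.372 and 0.0571; ranges over 9 alternatives 0.000165 to 0.585 and 3e-10 to 0.997). Against windows 1000 bp from the summits the C/EBP ratio was 0.990. The GATA string occurred in 337 windows against 334. Against low-ranked relaxed regions, which were not matched on GC content (41.9% against 39.2%) or TSS class (12.5% against 41.6% near a TSS), with 268, its ratio was 1.26 (adjusted exact p = 0.0169; range over 9 alternatives 0.000107 to 1), and for the 4236 pooled regions with a q value under 0.05 it occurred in 767 against 620 windows (ratio 1.24). Of 2080 6-mers, 77 were enriched and 167 depleted; of the 77, 55 were also enriched without replicate 2 and 53 without replicate 3. GAGAGA had the lowest p, at 19.2% of summit windows against 5.77%, while CCAGGA led the depleted ones at 1.55% against 6.52%.

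**Figure D2:**
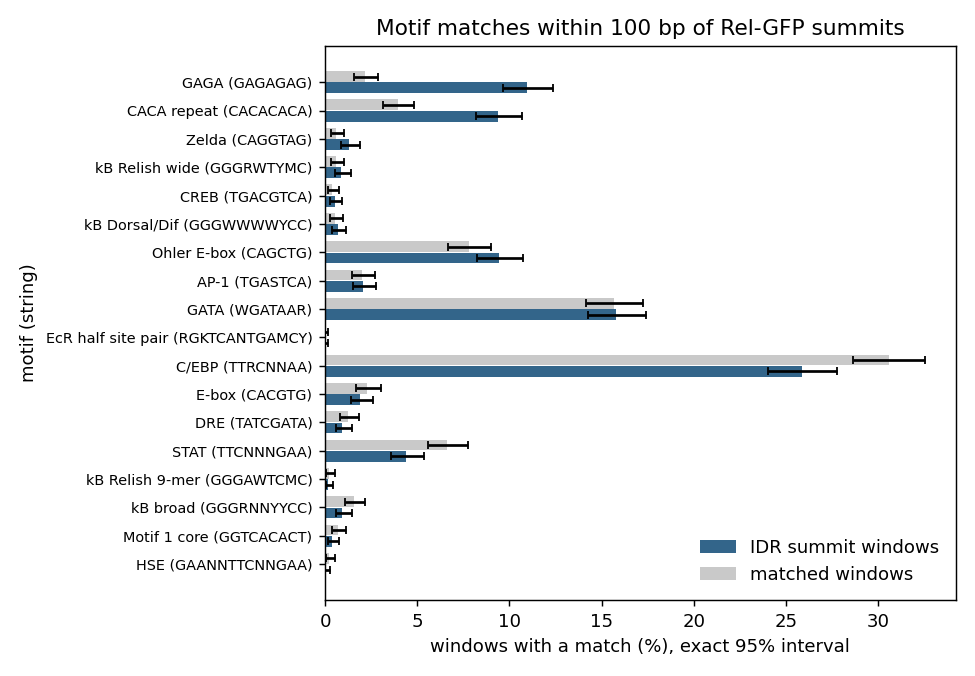
Share of windows with a match to each of 18 motif strings, in percent with exact 95% intervals, for 2133 windows of 100 bp either side of IDR summits (blue) and as many matched windows (grey). GAGAGAG reaches 10.97% against 2.16%, and the broad kB string 0.938% against 1.55%.

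Some genes of the Imd pathway carried stronger peaks and the listed antimicrobial peptide genes carried none, but neither list could be told from random lists. Of 15 antimicrobial peptide genes, among them AttA and AttB, 0 had an IDR summit, where length-matched lists had a mean of 0.337. The Bomanins, short immune peptides of the Toll pathway such as BomS1 and BomS2, also had 0 of 12 (mean of random lists 0.317). With means this low, a lack of summits could not be told from chance (adjusted permutation p = 1 for both lists). Of 30 Imd pathway genes, 5 were bound, against 3.05 in random lists (adjusted permutation p = 0.924). The pathway's adaptor imd had a peak ranked 39 at its promoter (2R:18413492-18413887, summit 91 bp from the TSS, signal 304). The negative regulator dnr1 had 3 summits, the strongest ranked 33 in an intron (2R:22569929-22570062, signal 318). Tab2, a partner of the kinase Tak1, and eff, a ubiquitin-conjugating enzyme, had intronic peaks ranked 611 and 946. The receptor PGRP-LE had 1 peak ranked 1436, in the top regions of replicate 3 but not of replicate 2.

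Of 19 Toll pathway genes, 6 were bound against 2.77 in random lists (unadjusted permutation p = 0.0762, adjusted 0.274; unadjusted 0.0192 with 7 genes bound without replicate 2). They include Gprk2 (rank 7, the peak shared with PNPase), the recognition protein GNBP3 (rank 154, promoter), Pli (rank 405, intron) and cact, the IκB of the pathway (rank 781, promoter). In the JAK-STAT list 3 of 12 genes were bound, Ptp61F (rank 91), Socs36E (rank 207) and Stat92E (rank 810), against 1.85 in random lists (adjusted permutation p = 0.924).

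The hormone, stress, heat shock and ribosomal protein lists had more bound members than random lists by the unadjusted test on the IDR list, and none passed after adjustment. With 1 replicate left out, 2 of these lost the unadjusted call, heat shock without replicate 2 (3 genes, unadjusted permutation p = 0.18) and JNK and stress without replicate 3 (6 genes, 0.139). By the length-matched permutation test, 0 of 18 lists had an adjusted p under 0.05, and 4 had an unadjusted p under 0.05. Of 15 ecdysone response genes 10 were bound, against 4.59 in random lists (unadjusted permutation p = 0.0086, adjusted 0.155). The nuclear receptor genes Eip78C, Hr4, Eip75B and EcR had best peaks ranked 72, 79, 85 and 131, and Eip75B held 11 summits and EcR 7. Of 15 JNK and stress genes 7 were bound against 3.15 (adjusted permutation p = 0.18), including puc, the JNK phosphatase, with 5 summits (best rank 144), Keap1 (357), cnc (442) and msn (499). This list passed when the nearest TSS took the summit (8 genes, adjusted permutation p = 0.0342) and without length matching (0.0126; range over 9 alternatives 0.0126 to 0.497). Of 15 heat shock genes 4 were bound against 1.09 (adjusted permutation p = 0.18), namely Hsp27 (rank 24), Hsp83 (101), Hsc70-4 (1962) and Hsp26 (2132). Of 88 cytosolic ribosomal protein genes 10 were bound against 4.38 (adjusted permutation p = 0.18), including RpS28b, RpL34b and RpL37A at ranks 415, 587 and 717. With the top 2133 regions of 1 replicate in place of the IDR list, 16 ribosomal protein genes were bound without replicate 2 and 15 without replicate 3, each with an adjusted permutation p of 0.0036 (range over 9 alternatives 0.0036 to 0.978). The ratio of bound ribosomal protein genes to random lists fell from 2.28 to 1.52 with the nearest TSS (7 genes) and to 1.07 without length matching (10 against 9.33). The ecdysone list, at 10 genes, had an adjusted permutation p of 0.0432 without replicate 2 and of 0.0648 without replicate 3 (range over 9 alternatives 0.0036 to 0.172). It passed in 5 of the 9, namely without replicate 2, with the 1066 strongest peaks, with the pooled regions with a q value under 0.05, with the nearest TSS and without length matching.

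Markers of the tissues that make up a larva showed no list past the threshold. Of 12 larval fat body genes 3 were bound, Lpin (rank 20), bmm (901) and Lsd-1 (1668), with 4 without replicate 2 and 2 without replicate 3. Of 14 haemocyte genes 1 was bound, ush, with 6 summits, and 2 without replicate 2. The salivary gland regulators fkh (rank 363) and CrebA (1033) were the bound members of a list of 12. Muscle genes had 3 of 14 bound (Mef2 at rank 556, Zasp52 at 1009, Tm1 at 1858), and neuron genes 2 of 11 (elav at 142, Syx1A at 873). Midgut genes had 2 of 10 (nub at 800, Myo31DF at 1903). Of 16 Hox and segmentation genes 3 were bound (hth, Antp and Scr, at ranks 915, 1540 and 1625; 1 without replicate 3), of 14 autophagy genes 3 (Atg1, Atg18a and Atg16, at 1036, 1090 and 1853; 5 without replicate 3), and of 9 clock genes 2 (vri at 50, cwo at 1250). Adjusted permutation p-values of these lists ran from 0.924 to 1. In all, 1485 of 13945 protein-coding genes (10.6%) were bound, with a median length of 7399 bp against 1989 bp for the others.

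**Figure D3:**
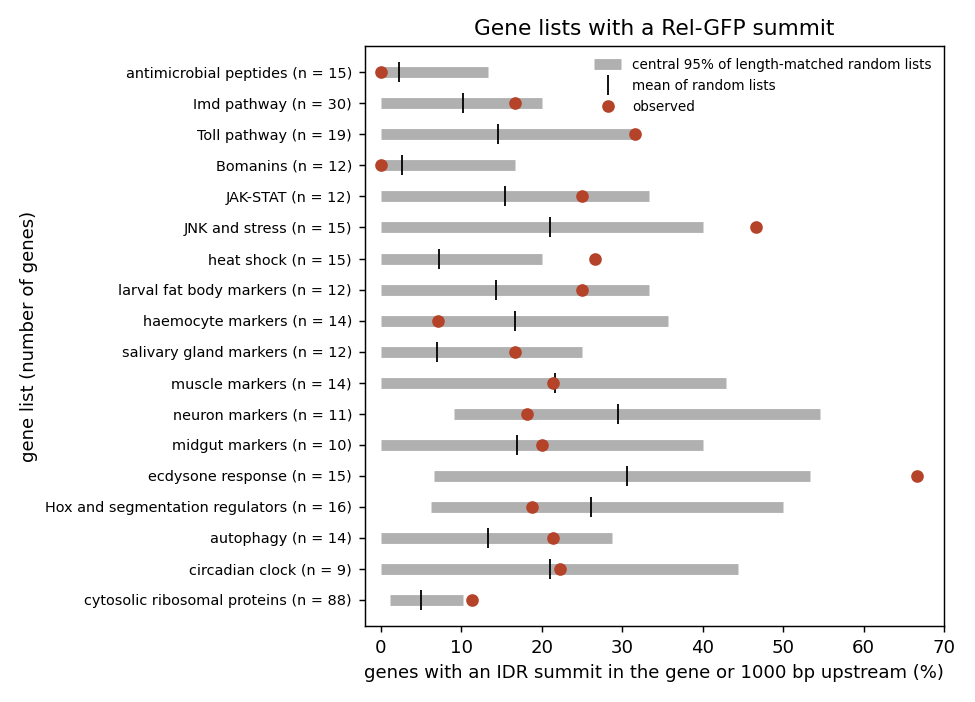
Percent of each list's genes with an IDR summit in the gene or 1000 bp upstream (red points), the mean of 10000 length-matched random lists (black ticks) and their central 95% (grey bars), with the number of genes per list in parentheses. Ecdysone response genes lie at 66.7%, and antimicrobial peptide genes and Bomanins at 0%.

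Peak density on the X chromosome did not pass a test against the large autosomes, and chromosome 4 had few peaks. Since larvae of both sexes were pooled, X is present in fewer copies than autosomes. The X held 363 peaks, 15.5 per Mb (exact Poisson 95% interval 13.9 to 17.1), and its density was 0.954 of that on 2L, 2R, 3L and 3R together (exact binomial p = 0.427). Densities on the autosome arms ran from 15.3 to 17.6 per Mb. Chromosome 4, which is largely heterochromatic, held 6 peaks, or 4.51 per Mb (interval 1.65 to 9.81). Without replicate 2 the X ratio was 0.883 (exact binomial p = 0.0356), and without replicate 3 it was 0.935 (p = 0.256, exact; range over 4 alternatives 0.0356 to 0.265). Among the 1066 strongest peaks it was 0.850 (exact binomial p = 0.0543), and among peaks over 500 bp from a TSS 0.917.

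The line carries a tagged copy of Rel, whose DNA maps to the native locus (3R:9044183-9047977, minus strand). No IDR peak and no region of the pooled relaxed list had its summit in Rel or within 5 kb of it, where the median gene had 3 such relaxed regions and 18.5% of genes had 0. Within 20 kb lay 2 IDR peaks, ranked 67 (3R:9031928-9032123, signal 252) and 1254 (3R:9033806-9034201), more than at 75.8% of protein-coding genes. The median gene had 1 IDR peak within 20 kb, and none of these counts was tested. In the relaxed lists the counts within 20 kb lay below the median gene. They were 6 regions in the pooled list (median gene 11), 5 in replicate 2 (12) and 10 in replicate 3 (11). Without replicate 3 there was 1 peak within 20 kb.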

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

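The tests of the 300 highest-ranked windows and of low-ranked regions in coding sequence were chosen only after the results were seen. So was the test of windows matched among those without lower-case bases. The same holds for the limit set for windows of 200 bp either side of summits and the values without 1 replicate. It also holds for both counts of peaks or regions outside the dm6 IDR list.

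Some peaks and regions lay outside the IDR list on the main chromosomes of dm6. On dm3, 5 IDR peaks fell on unassembled sequence (Uextra), at ranks 135 to 1058 of 2096, where no gene could be assigned. On dm6, 2103 pooled regions had a q value under 0.05 and were not in the IDR list. Of these, 36.9% had a summit within 500 bp of a TSS, and 28.1% overlapped a region among the top 4236 of both replicates. The pooled list mixes peaks with background, and no chance value was computed for this overlap, so these regions cannot be taken as signal.

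Rel is an NF-κB protein, yet kB strings were not enriched at the summits of its C-terminally tagged form. Dilution by weak peaks is argued against, at least for a motif in 10% or more of the strongest ones, since 3 of the 300 highest-ranked windows held GGGRNNYYCC, with an upper exact 95% limit of 2.89%. With windows of 200 bp either side, no excess over matched windows appeared, and the upper limit of the ratio was 0.842. Windows with up to 1 mismatch were also less frequent at summits than among matched windows (16.3% against 20.96%, upper limit of the ratio 0.884). This cannot decide whether the strings are too strict, since windows were matched on GC content and TSS class only. The ratio of GGGRNNYYCC itself was 0.612 against matched windows and 1.17 against shuffled windows, neither past the threshold. Windows with up to 1 mismatch were not compared with shuffled ones. The design has no second condition or untagged group here, so no biological explanation was tested. Recruitment through other proteins or through open chromatin stays open as untested. Forms of Rel without the C-terminal tag could not be seen, so these values do not describe where such forms bind.

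Summits were nearly absent from coding sequence, with 1 in the IDR list, 5 without replicate 2 and 2 without replicate 3. Assigning coding sequence before promoters left 6 summits there (0.281%; 14 without replicate 2 and 11 without replicate 3), against 17.1% of random positions, so the order of classes does not account for it. Of the 2133 lowest-ranked pooled regions, 9.10% had their summit in coding sequence, against 13.9% of random positions. Coding sequence can therefore enter the relaxed list. Since that list mixes peaks with background, this cannot show whether a strong peak could be called there. The lower GC content of the peaks is not enough either, because 5.30% of the windows matched on GC content and TSS class were centred in coding sequence. No biological explanation was tested.

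GAGA repeats were enriched at the summits. Among windows with no base in lower case, the reference's mark for repeats, 23 of 222 held GAGAGAG against 13 of 467 random windows, a ratio of 3.65 (95% interval 1.91 to 7.00), but these 467 were no longer matched to the 222. With 2220 windows matched on GC content and TSS class among those without lower-case bases, 48 held it, a ratio of 4.83 (95% interval 3.01 to 7.74; ratios of 4.49 without replicate 2 and 7.80 without replicate 3). Repeats marked in lower case are therefore not the whole of the enrichment. Of summit windows, 89.6% hold some lower-case base, as do 78.1% of matched windows, so the test covers few of them. It rests on 23 of the 234 summit windows with GAGAGAG, and repeats left in upper case were not told apart. The enrichment was also found away from promoters of protein-coding genes. Summits over 500 bp from a TSS had a ratio of 5 (95% interval 3.13 to 7.98). Windows were already matched on TSS class, so a higher share of promoters could not by itself produce the main ratio. Promoters of non-coding genes were not set apart. No biological explanation was tested.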

How the results depend on the processing

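Alternatives chosen only after the data were seen were the pooled regions with a q value under 0.05, matching on 50 length classes and, for motifs other than kB, windows of 200 bp, windows 1000 bp from the summits and shuffled windows. Among values under alternatives, 203 gave the same call or, for counts, a number within 1.5 times; 19 changed direction, 8 lost a call, 13 gained one and 13 moved further. Replicate overlap (51.1 to 65.5%) and the TSS share (26.4 to 52.3%, the latter range set by the TSS distance) passed their tests under every alternative run. The number of peaks was 2096 on dm3 and 2057 after merging; leaving out a replicate or taking the top part fixes that number by construction, so no such values were made. No paired analysis was possible because there is 1 group. The unknown depth limits how far a missing peak can be read.

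The cause was not tested for any of the following changes. The kB ratio passed its threshold, below 1, with windows of 200 bp (0.574). It lay above 1, without passing, against shuffled windows (1.17) and for GGGRWTYMC (1.44) and GGGWWWWYCC (1.24), whose ratios ranged from 0.555 to 1.11 and from 0.514 to 2.07 over 9 alternatives. Other motifs past the threshold fell from 4 to 2 among the top 1066 peaks and to 2 with windows of 50 bp, and numbered 6 with windows of 200 bp and 6 for the pooled regions with a q value under 0.05. Enriched 6-mers fell from 77 to 51 against low-ranked regions and, by construction, to 19 at a ratio of 2. The gene lists past the threshold numbered 0 with the IDR list and 1 to 2 with 1 replicate left out. They numbered 2 with the top 1066 peaks and 2 with the pooled regions with a q value under 0.05 (ecdysone and ribosomal), and 2 with the nearest TSS and 2 without length matching (ecdysone and JNK). The X ratio ranged from 0.883 to 0.935 with 1 replicate left out, passing only without replicate 2, and was 0.850 among the top 1066 peaks. Around Rel there were 1 to 2 peaks with 1 replicate left out, 1 among the top 1066 and 0 within 5 kb, in place of 2.

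Some list counts changed side of their random mean, none of them past the threshold. With the nearest TSS these were antimicrobial peptides (1 gene), Bomanins (1), muscle (3) and Hox genes (6). Counting summits within 500 bp of a TSS, they were Imd (2), JAK-STAT (0), autophagy (1) and clock genes (1). Among the top 1066 peaks they were muscle (2), midgut (1), autophagy (1) and clock genes (1). Without length matching they were muscle (3), neuron (2) and Hox genes (3), and with 50 length classes clock genes (2).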

Other observations

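The counts of summits per gene and of relaxed regions at list genes were chosen only after the results were seen, as were the genes named for them.

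The highest counts of summits per gene were 16 in sbb, 12 in shn, which encodes a zinc finger protein of Dpp signalling, and 11 each in jing, Tet and Eip75B. Next came tara with 10 and Eip74EF, Tlk, kirre and tai with 9 each. These counts were not corrected for gene length, which differed widely (34.7 kb for tara and 394 kb for kirre). Of all protein-coding genes, 48 held 5 or more summits, while 1106 held exactly 1. The 10 bound genes of the ecdysone list held 46 summits in all, and no expected number was computed.

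Antimicrobial peptide genes had regions in the relaxed pooled list, which mixes peaks with background. At 8 of the 15 there was at least 1 such region, against a mean of 4.01 in length-matched lists, but the best rank was 5483 of 30000, at edin, and the next 6273, at DptA. For the Bomanins, 3 of 12 had such a region (mean of random lists 3.32), with a best rank of 14841. Of the ribosomal protein genes 58 of 88 had one (mean 33.7), as did all genes of the fat body (12, mean 7.56), neuron (11, mean 9.99) and ecdysone lists (15, mean 13.5). No test was run on these counts.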
